A study of Caenorhabditis elegans with 2 samples.

How the data were processed

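Peak lists from ChIP-seq of whole L4 larvae of Caenorhabditis elegans were analysed, for 2 biological replicates of 1 group that express Y48G9A.11 with TY1, enhanced GFP and 3xFLAG tags. Per the labels, the tag was inserted by CRISPR, chromatin was sheared by sonication to fragments of 200 to 800 bp, and immunoprecipitation used an antibody against GFP. Replicate numbers were taken from the labels, which name them biological replicates.

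The authors deposited peak lists on genome build ce11: for each replicate alone, and for both replicates together, a ranked list of candidate peaks and a thresholded list, with a further thresholded list called conservative. Per the deposited list of files, the peaks were derived from filtered alignments and a control, and thresholded lists also from a further file that is not described there. The aligner, the peak caller and their versions are not given in the sources used here. Each deposited peak has a signal value, a score that the authors' peak caller gave relative to a control on a scale that is not stated, and the position of its summit. The deposited ranked lists also give the −log10 of the irreproducible discovery rate (IDR), which compares ranks between 2 lists of peaks. The lowest score in every thresholded list was 830, which corresponds to an IDR of 0.0100. Signal values from pooled lists were about the sum of the replicates' values, so their sizes are not comparable between a pooled list and that of a single replicate. No read counts were used here, so depth per sample is unknown and no interval covers it. Confidence intervals are exact (Clopper-Pearson) at 95%, treat peaks as independent and cover counting error only.

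The main list was the thresholded list of both replicates that is not called conservative (2228 of 93610 candidates). The conservative list held 2171 peaks, the list of replicate 1 held 1358 and that of replicate 2 held 1200. A total of 1818 main peaks stood unchanged in the conservative list. Since the series-wide lists were made from both replicates together, the replicates were compared through their own lists.

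Genes came from the Ensembl annotation release 115 of WBcel235 (46890 genes on the nuclear chromosomes, 19973 of them protein-coding), whose chromosomes are those of ce11; tRNA products came from the RefSeq annotation of the same assembly. A gene's 5' end window ran from 1000 bp upstream to 200 bp downstream. Overlaps were found with bedtools 2.31.1 (at least 1 bp); other steps used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9. Random placement kept the chromosome and was drawn 10000 times; single comparisons used 100000 permutations. The X share and the central share were tested with exact binomial tests against gene 5' ends. Kinds of gene with at least 20 background genes and 39 lists fixed before the data were examined, each with at least 10, were tested with Fisher's exact test. The background was genes with a candidate peak in the window, protein-coding for the lists (12282, of which 1225 had a main peak). Lists held protein-coding genes, so the miRNA genes of the heterochronic list were not tested. The 6-mers were counted in 100 bp around the summit and in 100 bp at 250 to 350 bp from it, on sides alternating by rank. All adjustments used Benjamini-Hochberg at a threshold of 0.05.

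The tests were tested on simulated data. For the gene lists, over 12282 genes, 100 of 100 lists given a higher share were found and 1 of 620 unchanged ones was called. The raised lists were among the largest, and their rise was larger than that of most real lists. How often smaller lists or smaller rises would be missed was therefore not shown. Genes were drawn independently, so the effect of genes that share a peak was not simulated. For the 6-mers, 5 of 5 planted ones were found among 2080, and 2 of 1530 that share no stretch of 4 bases with a planted one were called; this limit was set after 6-mers overlapping planted ones had been called with them. For the promoter share, 2 of 100 sets of 500 random positions passed.

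Named genes followed a rule fixed beforehand: genes with the summit of one of the 25 strongest peaks in their window, the 4 members with the strongest peak of each list or kind of gene past the threshold, up to 2 members of the others, and the tagged gene. A peak in the chemoreceptor list that this rule would name is not reported here. Alternatives were the conservative list, the stronger 50% of peaks, each replicate's own list, windows of 500 and 2000 bp, other backgrounds and expectations, assignment to the nearest 5' end, 8-mers, a centre of 200 bp, the opposite flank, and other definitions of shared peaks. Added after seeing the data were protein-coding 5' ends, lists without peaks near tRNA genes and lists without peaks that overlap a stronger listed peak. The text lists of the deposited files were read for their descriptions and hold no measurement.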

Results

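Whole Caenorhabditis elegans animals were collected at the L4 larval stage, at 47.5 hours. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) mapped the places on chromatin recovered with the protein of the gene Y48G9A.11. The endogenous gene had been edited with CRISPR to add TY1, enhanced GFP and 3xFLAG tags, and an antibody against GFP pulled down the fusion protein. All samples belonged to 1 group of 2 biological replicates, so no condition was compared with another. No sample without the tag or with another tagged protein was among them. At no set of genes could binding by the protein therefore be told apart from general capture of highly transcribed loci. The questions the design allows are where the peaks lay, at which genes and sequences, and how far the replicates gave the same places. The values analysed were peak lists, and the depth of each sample is unknown. The main list, made by the authors from both replicates, held 2228 peaks with a median signal value of 132.3 and a range from 2.1 to 3680.4. Signal values are the authors' own scores per peak and are used here to rank, describe and compare peaks.

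The strongest peaks lay mostly outside protein-coding genes and upstream of 5' ends, often between divergent genes, and were listed in both replicates. The peak with the highest signal, 3680.4 in the main list (1885 in replicate 1 and 1809 in replicate 2), had its summit at position 15025966 of chromosome II in genome build ce11 (peak 15025745 to 15026150), between the divergent genes cmtr-1, at -148 bp from its 5' end, and the snoRNA gene Y53F4B.47, at -73 bp. The next peak, with a signal of 2907 (1453 and 1450.3), had its summit at II 12919353 between wago-4, which encodes an Argonaute protein, and F58G1.2. A peak with a signal of 2852 at IV 1659255 lay at -436 bp from rps-28 and at -855 bp from Y41D4B.4. The product of rps-28 is a protein of the small ribosomal subunit. The summit at IV 9147173, with a signal of 1957, fell in the windows of aly-2 on the plus strand and of rpb-12 and daf-10 on the minus strand. The gene rpb-12 encodes an RNA polymerase subunit.

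Of the 25 peaks with the highest signal, 24 had their summit in the 5' end window of at least 1 gene and 16 in windows on both strands. The peak without such a window was at IV 12621881, with a signal of 1768, and its nearest gene was ark-1. All 25 overlapped a peak in each replicate's own list. Other pairs of genes that shared such a peak were rbd-1 with T23F6.3 (signal 1305), strm-1 with cic-1 (1272) and ctnb-1 with klp-15 (1259.9). Further pairs were timm-23 with F15D3.6 (1211), pph-5 with Y39B6A.3 (1134), mrpl-49 with rpl-28 (993.9), pmlr-1 with ric-19 (970.6) and F53H1.4 with ddx-46 (929.8). The gene cic-1 encodes cyclin C, klp-15 a kinesin, timm-23 a subunit of the mitochondrial protein import machinery and mrpl-49 a mitochondrial ribosomal protein. The peak at IV 14464268 (signal 1498) lay at -249 bp from dld-1, in the windows of 2 piRNA genes, 21ur-3995 and 21ur-3824, and of the ncRNA gene LLC1.120. A peak with a signal of 1051.6 was shared by cox-10, Y38E10A.33 and the ncRNA gene Y38E10A.30, and one of 986.5 by F10E9.4, F10E9.5 and F10E9.7. R04F11.2 and R04F11.5 shared a peak of 1328, and Y39B6A.13 shared one of 1287 with the ncRNA gene Y39B6A.74. Peaks at F13B12.1 (1860.2), nyn-1 (1478), the ncRNA gene C46C2.12 (1243), dcap-1 (1188), H35B03.2 (1074), mecr-1 (981.2) and haf-2 (951.7) lay in windows on a single strand.

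The replicates shared most of their places. Of the 1200 peaks in the list deposited for replicate 2, 856 (71.3%, exact 95% confidence interval 68.7 to 73.9) overlapped a peak of replicate 1 by at least 1 bp, against 0.804% when the peaks of replicate 1 were placed at random on their own chromosomes (one-sided permutation test, p = 0.0001, the smallest that 10000 placements can give). In the other direction, 845 of 1358 peaks (62.2%) were shared. Across 827 pairs of shared peaks, Spearman's rho of the signal was 0.832 (permutation p = 1e-05, the smallest possible). This is a correlation across peaks, which are not independent replicates. Without the strongest 10% of shared peaks, rho was 0.770 over 744 pairs. Presence in both replicates' own thresholded lists differed with strength. In the strongest 10% of the main list, 222 of 223 peaks were in both, while 714 of all 2228 main peaks (32%) were in neither. Each list has its own threshold, so absence from it does not show that a replicate lacked signal there.

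**Figure D1:**
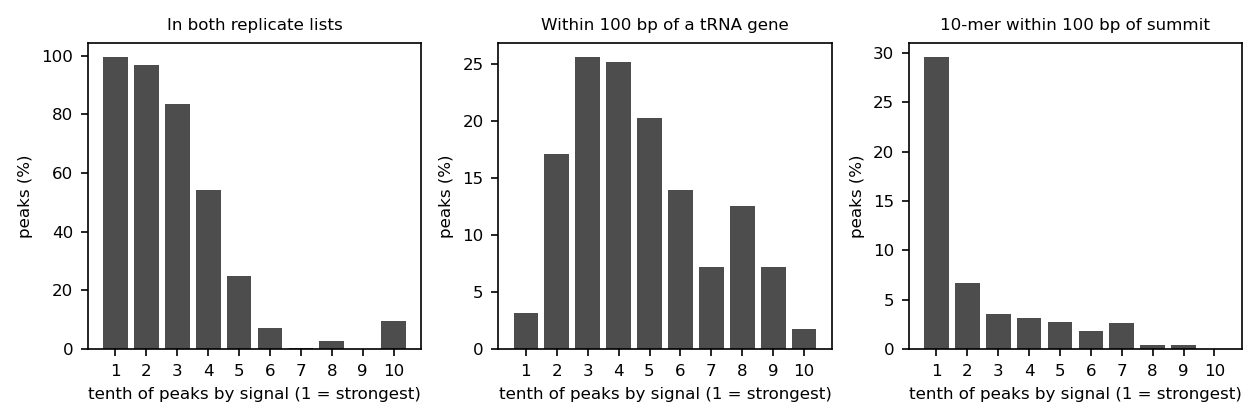
Bars give the percentage of main peaks in each of 10 groups of nearly equal size, ordered by signal from 1 (strongest) to 10, that overlapped a peak in both replicates' own lists (left), lay within 100 bp of a tRNA gene (middle) or held the sequence ACGACACTCC or its reverse complement within 100 bp of the summit (right); the vertical scales differ. Peaks in both replicate lists made up 99.6% of group 1, 24.8% of group 5, 0.448% of group 7, 2.69% of group 8, 0% of group 9 and 9.46% of group 10, where all 21 of them overlapped a stronger listed peak. Peaks at tRNA genes were most frequent in group 3 (25.6%), and the sequence was present in 29.6% of group 1 and 6.73% of group 2. The sequence was chosen on peaks of group 1 on chromosomes I, III and V, which are counted here.

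Most summits lay near an annotated 5' end when all kinds of gene were counted. Summits of 1485 peaks (66.7%, interval 64.7 to 68.6) lay between 1000 bp upstream and 200 bp downstream of an annotated 5' end, against 34.3% at random positions on the same chromosomes (two-sided permutation test, p = 0.0001, the smallest possible). Both strands had such a window at 626 summits (28.1%, interval 26.2 to 30), against 7.30% at random (permutation p = 0.0001). With 5' ends of protein-coding genes only, a set chosen after seeing the data, the shares were 44.2% against 21.5% and 12.9% against 2.2%. Outside protein-coding genes lay 1202 summits (53.9%), in introns 584 (26.2%), in coding exons 303 (13.6%) and in UTRs or other non-coding exons 139 (6.24%). Coding exons make up 24.6% of the genome. Peaks in 5' end windows were stronger than others, with a median signal of 145.9 (n = 1485) against 112.3 (n = 743; two-sided permutation test of the medians, p = 1e-05, the smallest possible). The difference in medians was 33.6 here, and 19.7 and 20.6 in the lists of replicates 1 and 2, whose signals are on a lower scale.

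Genes transcribed into small structural RNAs stood out among the kinds of gene. A main peak lay in the window of 347 of 524 tRNA genes that had any candidate peak there (66.2%), of 47 of 92 snRNA genes (51.1%) and of 34.9% of 298 snoRNA genes, while 1225 of 12282 protein-coding genes (9.97%) had one. These 3 kinds were higher than the rest of the genes (odds ratios 18.6, 8.72 and 4.55; Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 10 kinds, adjusted exact p = 7.24e-208, 2.34e-21 and 3.74e-28). Genes that share a peak are counted separately, so these p-values and those of the other kinds of gene below are too small. The odds ratio of tRNA genes was 11.2 in the list of replicate 2 and 27.9 with all genes as background, which also moved that of snoRNA genes to 8.21. The strongest peaks in tRNA gene windows lay at -564 bp from the lysine tRNA gene F15D3.t1 (signal 736.6) and at -935 bp from the lysine tRNA gene ZK994.t2 (481.1), both beyond 100 bp of the gene. The next lay at -33 bp from the alanine tRNA gene T07D10.t1 (471.7) and at -60 bp from the serine tRNA gene T02G6.t1 (468.9). Among snoRNA genes they were at Y53F4B.47, W03C9.9 (682.8), C51F7.3 and C51F7.4 (1 shared peak, 547.0), and among snRNA genes at R07E5.16 (343.6), sup-39 and mir-1831 (1 shared peak, 337.0) and sup-6 (328.2).

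Within 100 bp of a tRNA gene, a distance chosen after seeing the data, lay 298 main summits (13.4%, interval 12 to 14.9), against 0.142% at random (permutation p = 0.0001), and 311 of all 612 tRNA genes (50.8%) had a summit that near. The list of replicate 1 held 233 such peaks and that of replicate 2 held 183. Summits at tRNA genes were a median of 24 bp inside the gene from its 5' end, and the genes have a median length of 72 bp. The exact sequence of 472 of 612 tRNA genes (77.1%), 46 of 129 snRNA genes (35.7%) and 3 of 346 snoRNA genes (0.867%) occurred at 2 or more places in the genome. Values at such genes are uncertain.

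Fewer piRNA genes (128 of 2628, 4.87%, adjusted exact p = 7.64e-30), pseudogenes (73 of 1155, 6.32%, adjusted exact p = 1.25e-07) and lincRNA genes (4 of 118, 3.39%, adjusted exact p = 0.00844) had a peak than other genes did. The odds ratio of piRNA genes was 0.388 here, 0.220 and 0.230 in the lists of replicates 1 and 2, and 0.107 with all genes as background. The 4 lincRNA genes were M04F3.7 (617.6), linc-44 (243.0), linc-92 (127.3) and linc-8 (114.6), and their call was lost with all genes as background and in the list of replicate 1. Protein-coding genes (odds ratio 0.815, adjusted exact p = 3.52e-06) and ncRNA genes (0.834, adjusted exact p = 0.00106) were also lower than all other genes against this background. Those other genes include the tRNA genes, of which 347 of 524 (66.2%) had a peak. No comparison of kinds without tRNA genes was made, so these calls do not show a depletion of protein-coding or ncRNA genes themselves. Both kinds turned higher (odds ratios 1.41 and 1.23) when all genes served as background, and the call of protein-coding genes was lost in the list of replicate 2. No difference was detected for miRNA genes (18 of 177, strongest peaks at cel-mir-2213 with 249.9 and cel-mir-4932 with 234.6) or antisense RNA genes (3 of 62, strongest peak at anr-58 with 358.4).

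Among protein-coding genes, lists that include ribosomal proteins, oxidative phosphorylation, the cell cycle and the germ line had peaks more often, and chemoreceptor, F-box, innate immunity, nuclear hormone receptor and neuropeptide genes had them less often. Of 76 cytosolic ribosomal protein genes with a candidate peak, 35 (46.1%) had a main peak, against 9.75% of other genes (odds ratio 7.90, adjusted exact p = 2.14e-14, Fisher's exact test over 39 lists). The odds ratio was 4.88 when each peak was given to the nearest 5' end alone and 12 with all genes as background. The strongest were at rps-28, rpl-28 (993.9), rpl-33 (840.4) and rpl-35 (768.4). Mitochondrial ribosomal protein genes had peaks at 18 of 61 (29.5%, adjusted exact p = 9.58e-05), led by mrpl-49, mrpl-11 (573.7), mrps-7 (552.3) and mrpl-40 (463.5). Oxidative phosphorylation genes had them at 14 of 40 (35%, adjusted exact p = 9.58e-05), led by cox-10, cox-16 (647.0), nuo-6 (509.5) and cox-5B (474.1). For translation factors the count was 11 of 42 (26.2%, adjusted exact p = 0.00650), with eif-3.E (802.5), eif-6 (418.6), eif-3.B (392.0) and eif-2Bgamma (337.0) the strongest. The peak of eif-2Bgamma, at -858 bp from its 5' end, is that of the snRNA genes sup-39 and mir-1831. The peak of eif-6 is shared with the proteasome gene pbs-2.

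Genes of the cell cycle and DNA replication had peaks at 15 of 44 (34.1%, adjusted exact p = 9.58e-05), with cdc-48.1 (500.5), pcn-1 (346.8), the sliding clamp of DNA replication, the cyclin B gene cyb-1 (341.3) and mcm-2 (285.3) the strongest. Germline and oocyte genes had them at 13 of 42 (31.0%, adjusted exact p = 0.000712), led by syp-2 (647.0, the peak it shares with cox-16), glh-1 (429.5), cpg-1 (381.2) and pos-1 (330.3). Chaperone genes had peaks at 18 of 75 (24.0%, adjusted exact p = 0.00139), among them dnj-22 (817.6), cyn-15 (655.5), cct-8 (621.7) and hsp-60 (461.3). Tubulin, kinesin and dynein genes had them at 11 of 40 (27.5%, adjusted exact p = 0.00509; klp-15, tba-2 with 484.2, zen-4 with 379.2 and tbb-1 with 287.6). Histone genes had them at 12 of 46 (26.1%, adjusted exact p = 0.00509; hcp-3 with 422.4, his-67 and his-68 with a shared peak of 296.2, and his-63 with 182.1).

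The remaining 5 lists that were higher began with RNA polymerase and Mediator subunits (14 of 64, adjusted exact p = 0.0134; rpb-12, cic-1, taf-8 with 753.4, rpb-3 with 645.1). Proteasome subunits were also higher (8 of 29, adjusted exact p = 0.0158; pas-4 with 645.1, the peak it shares with rpb-3, pbs-2 with 418.6, rpt-2 with 377.9, rpn-3 with 200.0), as were nuclear pore and import genes (10 of 43, adjusted exact p = 0.0205; npp-13 with 813.8, npp-6 with 308.8, npp-23 with 300.4, npp-3 with 280.4). Chromatin and synMuv genes (16 of 84, adjusted exact p = 0.0221; lin-9 with 349.0, set-21 with 326.7, set-16 with 298.8, lin-54 with 271.1) were higher too, and so were splicing factors (11 of 50, adjusted exact p = 0.0292; prp-8 with 475.3, prp-19 with 387.9, sna-1 with 305.0, smn-1 with 234.6). Some of these peaks are shared with genes of other lists or kinds: pbs-2 shares its peak with eif-6, smn-1 with cel-mir-4932 and prp-8 with bath-42. Genes that share a peak are counted separately, so these p-values are too small. In the authors' conservative list 11 lists passed, not 19, and 7 of the 14 higher lists kept their call there. Under every setting tried, the calls of cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, the cell cycle and chaperones held. The call of tubulins, kinesins and dynein was lost only in the list of replicate 2, and that of germline genes only in the list of replicate 1. Proteasome and chromatin calls were lost in the list of replicate 2, the conservative list, the stronger 50% of peaks and with the nearest 5' end. The chromatin call was also lost with a window of 500 bp. RNA polymerase and Mediator lost their call in the list of replicate 1, the conservative list and the stronger 50% of peaks. The calls of histones, translation factors, splicing factors and the nuclear pore were lost in the conservative list and with at least 1 other setting.

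Chemoreceptor genes had peaks at 9 of 502 (1.79%, adjusted exact p = 2.99e-12), with srd-4 (426.6) and sre-23 (342.4) the strongest. F-box, MATH and BATH genes had them at 6 of 258 (2.33%, adjusted exact p = 3.34e-05; bath-42 with 475.3, bath-41 with 389.1, fbxa-83 with 170.3, fbxc-44 with 96.0). The peak of bath-42, at -677 bp from its 5' end, is the one it shares with prp-8, at -313 bp. Innate immunity genes had them at 4 of 211 (1.90%, adjusted exact p = 6.68e-05), which were clec-104 (192.9), clec-126 (178.5), clec-87 (137.4) and clec-169 (124.5). Nuclear hormone receptor genes had them at 4 of 145 (2.76%, adjusted exact p = 0.00595; nhr-255 with 161.7, nhr-142 with 127.3, nhr-47 with 125.8, nhr-236 with 98.7). The peak of nhr-142 is the one it shares with the lincRNA gene linc-92. Of 66 neuropeptide and insulin genes, ins-39 (166.6) had a peak (adjusted exact p = 0.0279), a call lost in 5 of the settings, among them the conservative list and the list of replicate 2.

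No difference was detected for 20 lists, of which 6 passed the threshold under at least 1 other setting. Small RNA pathway genes were higher in the stronger 50% of peaks and in the list of replicate 1, and V-ATPase subunits were higher with a window of 2000 bp (7 of 21). Lower were cuticle collagens (window of 500 bp), detoxification enzymes (window of 500 bp, or all genes as background), hedgehog-related genes (window of 2000 bp, or without tRNA peaks) and bHLH, GATA, T-box, Sox and forkhead factors (window of 2000 bp). The values that follow are those of the main setting. Genes of the moulting cycle (0 of 15), epidermis (0 of 18), intestine (0 of 24) and pharynx (0 of 16) had no main peak, and adjusted exact p was between 0.256 and 0.467 for these 4. Cuticle collagens had peaks at 5 of 103 (adjusted exact p = 0.164; col-8 with 786.2), detoxification enzymes at 6 of 126 (0.0946) and hedgehog-related genes at 1 of 54 (0.0777). Body wall muscle genes had them at 1 of 30 (0.451), synaptic and neuronal genes at 2 of 36 (0.624) and sperm genes at 2 of 48 (0.332). Homeobox genes had them at 2 of 45 (0.411) and bHLH, GATA, T-box, Sox and forkhead factors at 1 of 49 (0.156). Small RNA pathway genes had them at 8 of 49 (adjusted exact p = 0.239; wago-4), autophagy and lysosome genes at 9 of 57 (0.266) and heterochronic genes at 2 of 11 (0.406; lep-2 with 290.3). Vulval signalling genes had them at 1 of 25 (0.573; egl-17 with 301.0), sex determination genes at 2 of 25 (adjusted exact p = 1) and insulin, TGF-beta and dauer genes at 2 of 31 (0.785). V-ATPase subunits had them at 1 of 20 (0.753) and aminoacyl-tRNA synthetases at 1 of 27 (0.573; ears-2 with 131.0).

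**Figure D2:**
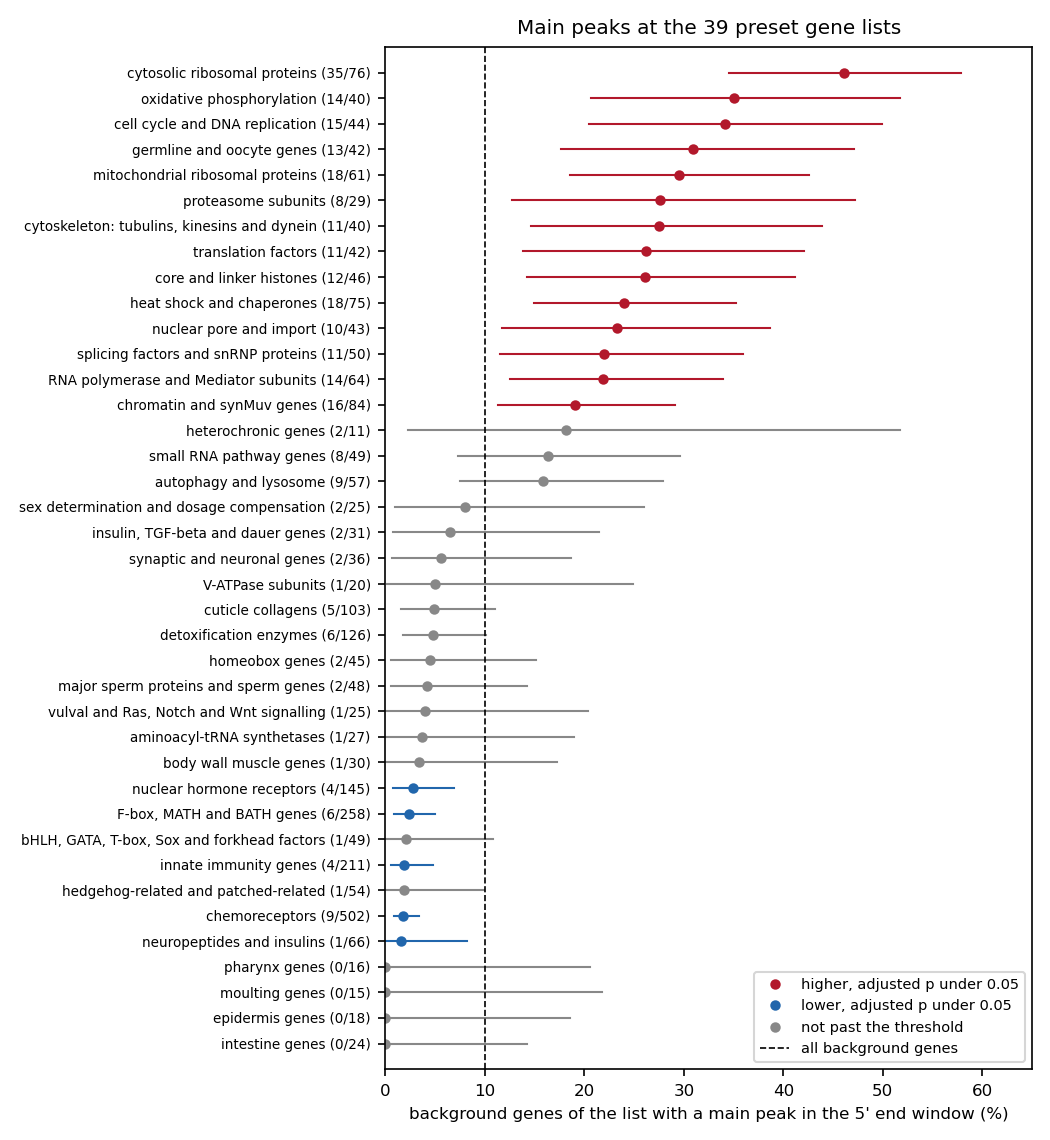
Points give the percentage of the background genes of each of 39 preset lists that had a main peak in the 5' end window, and lines the exact 95% confidence interval; counts stand beside the names, colours give the call after adjustment and the dashed line marks all background genes. Cytosolic ribosomal protein genes were highest at 46.1%, and 14 lists were higher and 5 lower than the other genes.

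Chromosome X held few peaks apart from those at tRNA genes. It had 224 main peaks (10.1%, interval 8.84 to 11.4), against 12.8% of gene 5' ends (exact binomial test, two-sided, p = 5.68e-05), and 131 of the 224 lay within 100 bp of a tRNA gene. Of the 46890 annotated 5' ends, 15363 were of piRNA genes, and IV held 42% of all. Of protein-coding 5' ends alone, 13.7% were on X (exact binomial p = 2.52e-07). Without tRNA peaks, an alternative chosen after seeing the data, X held 93 of 1930 peaks (4.82%, exact binomial p = 2.52e-32). On the autosomes, 1036 of 2004 peaks (51.7%, interval 49.5 to 53.9) lay in the central 50% of length, against 43.6% of gene 5' ends (exact binomial test, p = 5.11e-13). This call ended against chromosome length (50%, exact binomial p = 0.134) and turned against protein-coding 5' ends alone, of which 55.7% were central (p = 0.000380).

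**Figure D3:**
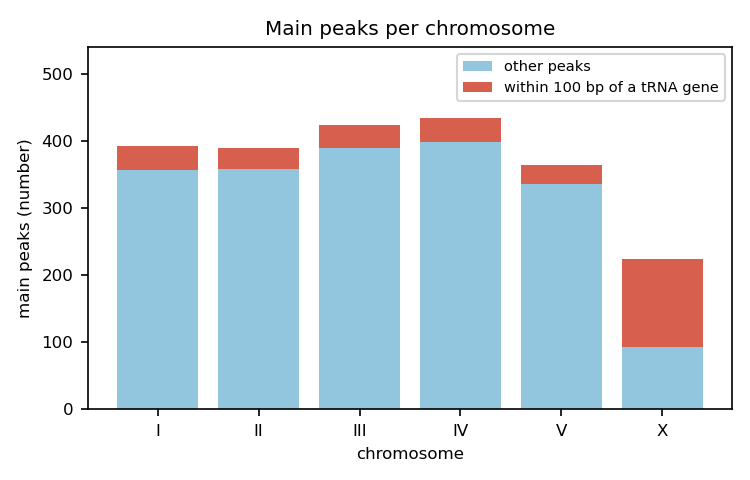
Stacked bars give the number of main peaks on each chromosome, divided into those within 100 bp of a tRNA gene and all others. Peaks at tRNA genes numbered 131 of 224 on X and between 29 and 36 on each autosome.

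Sequence at the summits was rich in G and C. The 100 bp around the summit had a mean GC content of 45.9%, against 35.7% in a flank of the same peaks, a difference of 10.2 percentage points ± 0.256 (SE over 2228 peaks; two-sided sign-flip permutation test, p = 1e-05, the smallest possible), and 79.1% of peaks showed this direction. The difference was smaller, 6.74 percentage points, with a centre of 200 bp. Of all 6-mers, 645 were more frequent at summits than in flanks and 415 less frequent (exact McNemar test, Benjamini-Hochberg adjusted). The 6-mer ACGCGC was first, at 236 summits and 19 flanks (adjusted exact p = 4.72e-46), followed among those more frequent by GCGCGC (187 and 20) and CGCGCC (220 and 35). Of the 421 more frequent on chromosomes I, III and V, 312 (74.1%) were also more frequent on II, IV and X. The more frequent 6-mers held a mean of 4.10 G and C bases and the less frequent ones 1.47. A CG pair was in 346 of the 645 and in 10 of the 415. The higher GC content of summits can give such 6-mers on any chromosome, so the split does not tell base composition from a preferred sequence.

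At the 298 peaks near tRNA genes, CGAACC was present at 142 summits and 4 flanks and GTTCGA at 147 and 10. These match the conserved T-loop of tRNA genes. The peaks were selected for lying at tRNA genes, so their centres hold such sequence by selection. At the other 1930 peaks ACGCGC remained first, at 215 summits and 22 flanks (adjusted exact p = 4.03e-38), and CGACAC was at 209 and 44 (adjusted exact p = 5.07e-25). The 6-mers TAAAAA and AAAAAT were among the less frequent ones over all peaks, TAAAAA at 363 summits and 714 flanks.

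The tagged gene itself carried a peak of modest strength. Y48G9A.11 lies on the minus strand of chromosome III from 2112416 to 2116897 (ce11), and the main list had a peak from 2115916 to 2116239 with its summit at 2116078, in an intron, 819 bp downstream of the 5' end. Its signal was 118.4, which ranked 1353 of 2228. The list of replicate 2 also held it, with a signal of 55.4. In replicate 1 a candidate with a signal of 59.0 had a score of 804, below the lowest listed score of 830. The tag sits in this gene, and whether the peak is related to the tag was not tested. The peak is described only and is not read as an outcome.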

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

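Chosen after the results were seen were the tests of shared tRNA copies, of the 10-base sequence on II, IV and X, in shuffled sequences and in repeats, and of weak peaks, as were the distance of 100 bp and the use of the strongest 10% of peaks; the tests of neighbouring promoters and of general capture were written down before their results. With a single group, no biological explanation was tested.

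A signal appeared in candidates that the main list leaves out: 75 candidates reached the lowest listed score but were absent from it. The strongest had a signal of 3695.6, above that of any listed peak, with its summit at X 15811109 (peak 15810932 to 15811181) outside annotated genes, and candidates there had signals of 1910.5 in replicate 1 and 1979 in replicate 2. The next strongest lay at I 10947558 (868.7), nearest to the tRNA gene Y95D11A.4, and at X 293447 (722.8) and V 5284161 (655.2), each nearest to a protein-coding gene. Weaker ones included V 17123062 (382.5), nearest to the ribosomal RNA gene rrn-4.2. Thresholded lists were derived also from a further file that is not described, so why these candidates are absent is not known.

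Peaks at tRNA genes were weighed first. Sharing of reads between identical copies as the whole source is argued against by tRNA genes whose sequence occurs at a single place: 49 of 140 (35%) had a main summit within 100 bp, against at most 3.57% in random placements. The share was higher, 262 of 472 (55.5%), for sequences at 2 or more places (Fisher's exact test, p = 2.13e-05), and only exact copies were counted, so a part from shared reads stays open. Promoters of neighbouring protein-coding genes as the whole source are argued against by tRNA genes with no protein-coding 5' end within 1000 bp, of which 208 of 421 (49.4%) had a summit, against at most 2.14% at random. General capture of highly transcribed loci without contact by the tagged protein cannot be told apart from recruitment through another protein: 0 of the 298 peaks at tRNA genes held the 10-base sequence of the strongest peaks, but that sequence was chosen on peaks away from tRNA genes and is rare outside the strongest 10%, so the count decides nothing.

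A sequence of 10 bases, ACGACACTCC, was most enriched among the strongest 10% of peaks away from tRNA genes on I, III and V, where 40 of 128 peaks had it at the summit alone and 0 in the flank alone. Chance among many 10-mers is argued against by II, IV and X, where 21 of 88 such peaks had it at the summit and 0 in the flank (exact McNemar p = 9.54e-07), although related sequences had first been noticed on all chromosomes, so these were not blind. Base composition as the whole cause is argued against on II, IV and X, where 49 of 175 copies (28%, interval 21.5 to 35.3) lay within 100 bp of a main summit and 164 shuffled 10-mers with as many CG pairs reached at most 20% of 20 copies (second highest 8.70%, median 0%); the rule for this verdict was changed after values were seen, and over all chromosomes the highest shuffled share, 23.5%, lay inside the interval of 22 to 30.3 around 26%. Reads shared between copies of a repeat are argued against as the main source, since 29.3% of the copies near a summit (interval 21.2 to 38.5) shared a stretch of 24 bases with another copy, against 36.7% of 330 elsewhere; the test was corrected after its first result, which changed the share elsewhere and not the 29.3%. A candidate explanation that stays open is that the sequence is part of what the tagged protein recognises.

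Weak peaks in the conservative list were the third pattern: 88 of its peaks had a signal below the median candidate (31.5). All 88 overlapped a stronger listed peak, against 24 of the 2083 others, and the replicate signals matched to them summed to a median of 10.2 times the peak's own signal (quartiles 6.10 and 18.3), against 1.01 for the others. For weak but reproducible places the sum would be near the peak's own signal. However, the 88 peaks were selected for a low signal of their own, and listing required reproducible ranks in the replicates. A high ratio was therefore largely fixed by the selection and does not decide between such places and a shoulder matched to its stronger neighbour. The overlap of all 88 with a stronger peak does not use the ratio and is what a shoulder would give. In the main list 87 such weak peaks were present.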

How the results depend on the processing

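The alternatives without tRNA peaks, without overlapped peaks and with protein-coding 5' ends were chosen after seeing the data; all others were fixed beforehand. Of 86 values recomputed for the results of the design, 82 kept their direction and side of the threshold, or a count within 1.5 times. The central share of 51.7% was no longer past the threshold against chromosome length, and reversed (still 51.7%) against protein-coding 5' ends; the alternative's own construction shows the cause, since only the expected share changed. The number of gene lists past the threshold moved from 19 to 11 with the conservative list, and the cause was not tested. At the tagged gene the signal was 118.4 in the main list and 55.4 without replicate 1. Pooled signals were about the sum of the replicates' values, so these values are on different scales and show no change in strength. Without replicate 2, and in the stronger 50% of peaks, no peak was listed at the tagged gene. With all genes as background the odds ratios of protein-coding genes (1.41) and ncRNA genes (1.23) reversed. The peaks were unchanged and only the background differed, in which piRNA genes went from 2628 to 15363. How much each kind of added gene contributed was not tested. Over the lists of single replicates the promoter share was 73.8 to 76.2%, the X share 9.28 to 9.50%, the number of lists 15 to 18 and the number of 6-mers 833 to 850. Of 338 further values for single lists, kinds of gene and 6-mers, 303 kept their call, 33 kept their direction but lost it, and 2 reversed. Depth is unknown, so what it limits cannot be given.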

Other observations

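The values here were chosen after seeing the data and carry no test unless one is named. tRNA genes on all chromosomes had main peaks: the share with a summit within 100 bp was 137 of 276 (49.6%) on X and between 41.0% on V and 57.9% on II for the autosomes. X holds 45.1% of annotated tRNA genes and held 44% of the peaks at tRNA genes. By product, aspartate tRNA genes (19 of 27, 70.4%), valine (20 of 31, 64.5%) and lysine (29 of 46, 63.0%) had the highest shares among those with at least 20 genes, and histidine (5 of 20, 25%) and glutamine (7 of 27, 25.9%) the lowest; the differences between products were not tested. Peaks at tRNA genes had a median signal of 150.7, against 128.9 for the other peaks. They were few in the strongest 10% of the main list (7 of 223) and most frequent in the third group of 10 (57 of 223).

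The sequence ACGACACTCC lay within 100 bp of 10 of the 25 strongest summits and of 114 main summits in all, 66 of them in the strongest 10% and 0 in the weakest. These counts, and those of its copies below, include the peaks of I, III and V on which it was chosen for the strongest 10%. On II, IV and X, away from tRNA genes, the sequence was in the central 100 bp of 21 of the 88 strongest peaks and 37 of all 849. Of its 230 copies inside a 5' end window, 98 (42.6%) lay near a main summit, against 18 of 216 copies elsewhere (8.33%). The 8-mer most different between summits and flanks over all peaks, ACACTCCG (101 summits and 3 flanks), overlaps it.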
